A study of Homo sapiens with 6 samples.

How the data were processed

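Samples were 6 microdissected regions of a xenograft of the HT1376 bladder carcinoma cell line, grouped by the tissue region in the labels into 3 pimonidazole-high and 3 pimonidazole-low regions. Per the labels' protocols, sections of 10 µm were dissected, RNA was isolated with a kit for fixed, paraffin-embedded tissue, and RNA at 8 ng/µl in 9 µl was prepared for the Clariom S pico HT human assay. The regions were chosen by pimonidazole staining, with necrosis left out. The labels describe 1 xenograft and 1 mouse and do not pair a high with a low region. Replicate numbers follow the order of deposit and pair nothing. Because the regions share an animal, p-values over regions are too small.

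The authors deposited 1 normalized value per probe set and array, read here as log2 signal from its range of 2.30 to 18.6. The authors' software, background correction, normalization and annotation version are not given in the sources used here. The highest values exceed 16, the log2 of the largest 16-bit scanner value, so the scale is not a plain log2 of scanner signal, and the size of a fold depends on processing that is unknown here. Signal of mouse host RNA on these human probes was not separated from human signal.

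The table held 23921 probe sets, of which 2903 were controls. Of the 21018 others, 17520 had 1 gene symbol, 0 had several, and 3498 are unnamed here. All 17520 Entrez identifiers matched the RefSeq gene table, and 0 symbols needed an update. For the 15 genes with more than 1 probe set, the probe set with the highest mean over all 6 arrays stood for the gene, which left 17503 genes. Genes of the lists with no named probe set, such as CA9, were not analysed here. No gene was filtered for low signal in the main comparison.

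Differences (pimonidazole-high minus pimonidazole-low) were fitted on the deposited log2 values with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior had 4.18 degrees of freedom. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. For 42 gene lists with at least 5 measured genes, shifts were tested with camera (preset inter-gene correlation 0.01, adjusted over the lists), with camera using an estimated correlation, and with fry, which tests whether a list's genes move on balance one way. The lists, the tests and the alternatives were fixed before the data were examined. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment to the members of a list.

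Genes were named by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, or, where fewer than 5 passed in a direction, the 8 with the smallest p, given as not past. The direction with rises had 8 such genes, and the direction with falls had 0. To these it added 15 hypoxia genes whatever their p, and up to 4 members of each list described, those past the threshold first and then those with the smallest p. ALDOC, EDN1, MT1X, COL1A1, COL1A2, DCN, S100A4, SLC2A14, the genes leading the first principal component and the squamous genes given array by array were named after their values were seen.

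The 90th percentile of the 612 negative control probe sets of each array served as the limit of its background range, a choice made after seeing the data. These controls are of an intron-type class, and 23 antigenomic background probe sets were not used. The limit may therefore differ from the true background of an array. Array quality was measured as the area under the curve (AUC) that separates 2197 positive from the negative control probe sets, and it was 0.968 to 0.974 on the 6 arrays.

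The fit was tested on simulated arrays with the measured means and limma's fitted variances of the 17503 genes, drawn independently, and 200 changed genes, in 5 runs. It recovered 35.2% of genes changed by 1 on the log2 scale, 98.4% at 2, 99.6% at 3 and 100% at 4, and 4.52% of its calls were false. These shares do not carry over to the real arrays. There the 8 genes that passed differed by 2.11 or more, but HK2 (2.71, limma adjusted p = 0.156) and FAP (-2.91, 0.117) did not pass. A gene that was not called may therefore still differ by more than 2. A list shifted by 0.5 was found in 20 of 20 simulations with independent genes, and an unshifted list had an unadjusted p under 0.05 in 1 of 20.

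Alternatives were quantile normalization, centring on the median, scaling to the 75th percentile, leaving out the dimmest 25% of genes or all genes below the median brightness, an intensity trend with and without a robust prior, array weights, the mean over probe sets of a gene, leaving out each array in turn, a fold threshold of 2 and an adjusted p threshold of 0.1. Removing the HIF list's members from the other lists was added after seeing the data. Tests on the brightness of glycolysis genes and on FAP were run as well and are given as values without weighing.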

Results

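Gene expression was measured in a xenograft of HT1376, a human bladder carcinoma cell line, grown in the flank of a nude mouse to 0.7 cm in diameter (the series title spells the line HT1367). The mouse received pimonidazole, a compound that forms adducts in cells at low oxygen, and was euthanised after 1 h. Staining for pimonidazole on sections next to those dissected guided the microdissection of strongly stained (pimonidazole-high) and weakly stained (pimonidazole-low) tumour regions, and necrosis was left out. The data comprise 6 human expression arrays, 3 of pimonidazole-high and 3 of pimonidazole-low regions, with 17503 genes tested. The protocols describe 1 xenograft in 1 mouse, so the regions share an animal. Any p-value over regions is therefore too small, since it rests on the spread between regions of this tumour and holds no spread between tumours.

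The arrays had medians of 6.45 to 6.59 on the deposited log2 scale over the tested genes, and between 46.8% and 52.4% of genes lay above the 90th percentile of the negative control probe sets of their array. The mean pairwise correlation across genes was 0.980 within the pimonidazole-high group and 0.990 within the pimonidazole-low group. The percent of genes above that range was 48.9 ± 1.83 (SD, n = 3) in the pimonidazole-high and 51.3 ± 1.26 (SD, n = 3) in the pimonidazole-low group, and the hybridisation controls averaged 8.66 ± 0.16 and 8.47 ± 0.13. The number of arrays limits the precision, and an exact permutation test of 3 against 3 cannot go below p = 0.1 for a single gene. The comparison asks which transcripts differ between strongly and weakly pimonidazole-stained regions.

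Pimonidazole-high regions had higher levels of 8 genes, and 5 of these belonged to the fixed list of genes induced by hypoxia-inducible factors (HIF). SLC2A3, which encodes the glucose transporter GLUT3, rose by 4.35 ± 0.38 on the log2 scale (SE, n = 3 and 3 arrays), from 8.25 ± 0.68 to 12.60 ± 0.52 (SD), a 20.3-fold difference on the deposited scale. IGFBP3, which encodes an insulin-like growth factor binding protein, rose by 3.08 ± 0.28, and ADM, which encodes the vasodilator peptide adrenomedullin, rose by 2.98 ± 0.27. ERO1A, an oxidase of the endoplasmic reticulum that supports disulfide bond formation, rose by 2.17 ± 0.20, and BHLHE40, a transcriptional repressor, rose by 2.11 ± 0.20. Outside the HIF list, the arachidonic acid epoxygenase CYP2J2 rose by 2.86 ± 0.32, the gap junction gene GJB6 by 2.51 ± 0.29 and the arrestin-domain gene ARRDC3 by 2.51 ± 0.24.

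In limma these 8 genes had adjusted p of 0.0149 for SLC2A3, IGFBP3, ADM, ERO1A, BHLHE40 and ARRDC3, and 0.0416 for CYP2J2 and GJB6. All 3 pimonidazole-high values lay above all 3 pimonidazole-low values for each of the 8. Among the other named genes, PLIN2, SLC2A14, PGF, ATF3, FOS and TNFAIP3 lay just above the threshold, each higher with a limma adjusted p of 0.0523. In limma 0 genes fell past the threshold. At an unadjusted p under 0.05 there were 1531 genes (772 higher and 759 lower), against 875 expected by chance. Splits of the arrays that mixed pimonidazole-high with pimonidazole-low regions gave 323 to 1556 such genes. The 1531 genes are therefore not read as an excess tied to the staining. The groups did not overlap for 13.9% of all genes, against 10% by chance. The count of genes past the adjusted threshold rested on single arrays. It was 156 without pimonidazole-high replicate 1, 1 without pimonidazole-low replicate 1 and 1, not among the 8, without pimonidazole-high replicate 3. In limma it was 0 without pimonidazole-high replicate 2, pimonidazole-low replicate 2 or pimonidazole-low replicate 3, where 1226, 1475 and 873 genes had an unadjusted p under 0.05. The regions share 1 animal, so these p-values are too small.

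**Figure D1:**
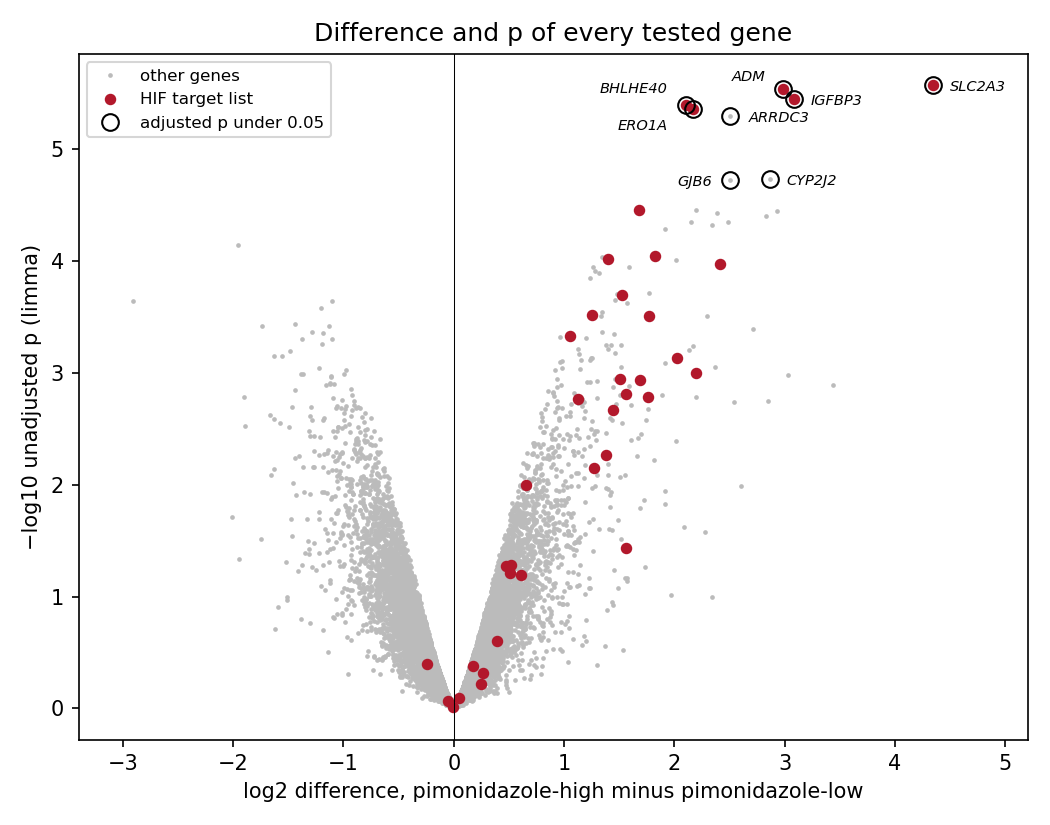
Difference in mean log2 signal between pimonidazole-high and pimonidazole-low regions (horizontal axis) against −log10 of the unadjusted limma p (vertical axis) for each of the 17503 tested genes. Red points are the 37 measured HIF target genes, rings mark the 8 genes with adjusted p under 0.05, and all 8 rings lie to the right of 0.

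The 8 genes with the smallest p among those with lower signal in pimonidazole-high regions did not pass the threshold and are given as values. TLL1, which encodes a tolloid-like metalloprotease, differed by -1.96 ± 0.27 (SE; limma adjusted p = 0.0709). FAP, which encodes a surface protease typical of activated fibroblasts, differed by -2.91 ± 0.47 and the metallothionein MT1F by -1.10 ± 0.18 (limma adjusted p = 0.117 for both). KCNJ5, ALOX5AP, ACKR3, COL27A1 and TDRD9 differed by between -1.74 and -1.13, with limma adjusted p of 0.129 to 0.156. The pimonidazole-high values of KCNJ5, ACKR3 and TDRD9 all lay within the range of the negative controls. So did ACKR3 in pimonidazole-low replicates 2 and 3, TDRD9 in pimonidazole-low replicates 1 and 3, and KCNJ5 in pimonidazole-low replicate 1. The sizes of these differences are therefore uncertain.

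Among 15 hypoxia genes fixed in advance, 14 were measured and CA9 was not analysed here. In limma, 1 of the 14 rose over all genes (ADM), and 9 rose adjusted over the list alone: ADM, ANKRD37, EGLN3, NDRG1, VEGFA, PDK1, SLC2A1, PGK1 and P4HA1. The differences of those other than ADM ranged from 1.12 ± 0.25 for the glucose transporter gene SLC2A1 to 1.82 ± 0.26 for ANKRD37. VEGFA, the vascular growth factor, was higher by 1.51 ± 0.31, from 12.60 ± 0.39 to 14.11 ± 0.51 (SD). The mitophagy gene BNIP3 differed by 0.51 ± 0.23, LDHA by 0.30 ± 0.23 and ANGPTL4 by 0.17 ± 0.20, without passing either adjustment. With 1 array left out, BNIP3 was 0.34 without pimonidazole-high replicate 1, LDHA was 0.11 and ANGPTL4 0.02 without pimonidazole-high replicate 2, and ANGPTL4 was 0.28 without pimonidazole-high replicate 1. BNIP3 and ANGPTL4 lay within the range of the negative controls on all 6 arrays, and EGLN3 did so on the 3 pimonidazole-low arrays. HIF1A, which encodes the oxygen-regulated HIF subunit, differed by -0.06 ± 0.23, and the proliferation marker MKI67 differed by -0.02 ± 0.19 with a sign that flipped when each array was centred on its median. The count over all genes was 4 without pimonidazole-high replicate 1 and 0 without pimonidazole-high replicate 2 or 3 or pimonidazole-low replicate 2 or 3. The p-values over these regions of 1 animal are too small.

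**Figure D2:**
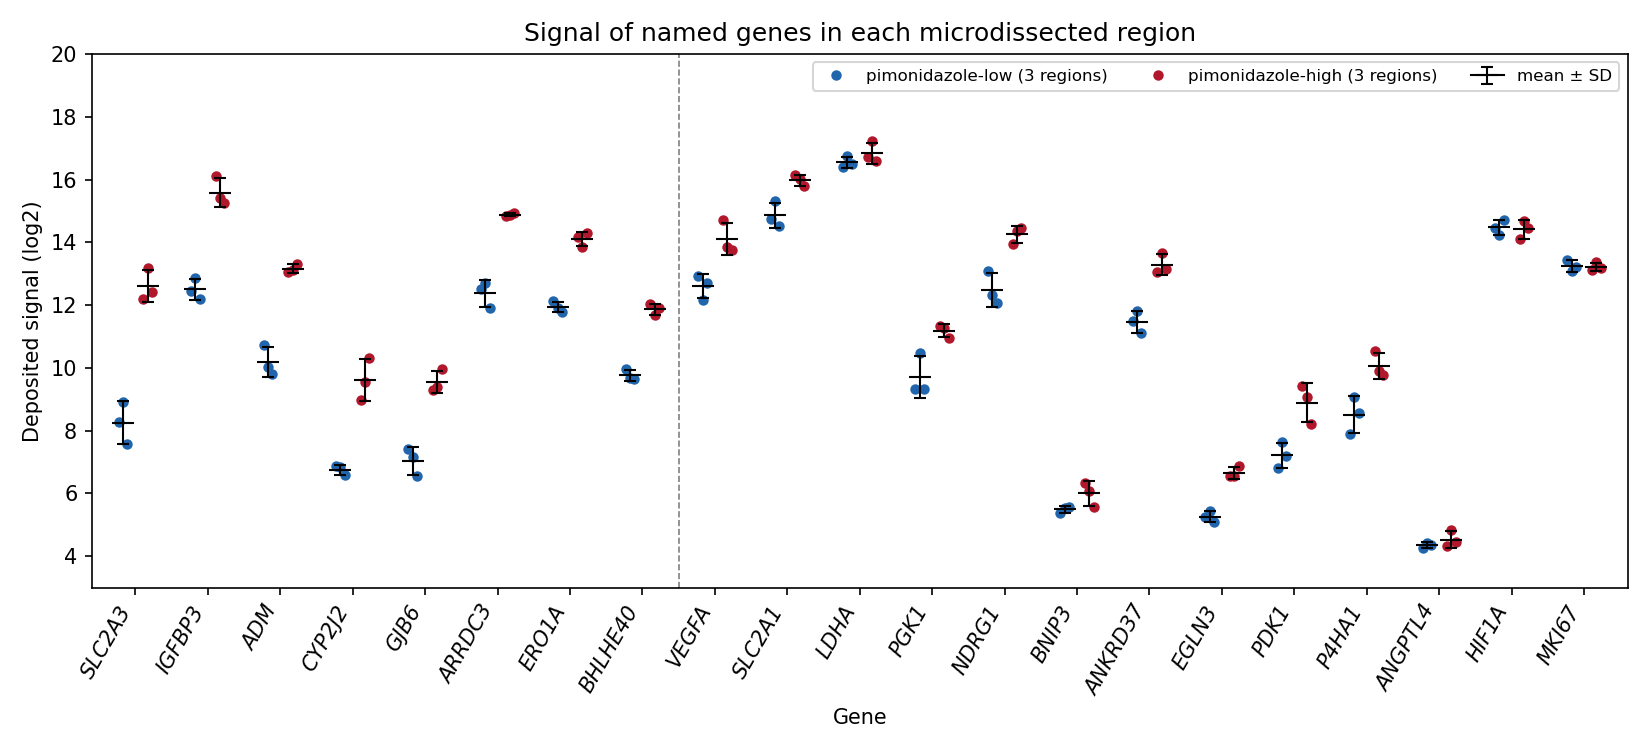
Deposited log2 signal (vertical axis) of each region for the 8 genes past the threshold (left of the dashed line) and the other 13 measured hypoxia genes fixed in advance (right of it). Points are the 3 pimonidazole-low (blue) and 3 pimonidazole-high (red) regions, and bars are mean ± SD. SLC2A3 goes from 8.25 to 12.60, while HIF1A and MKI67 overlap between the groups.

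Of 42 gene lists fixed before the data were examined, 16 shifted in camera with a preset correlation, 13 up and 3 down. With an estimated correlation, 2 of them kept their call, the HIF targets and a published 15-gene hypoxia classifier. These are nearly the same genes, since 13 of the classifier's 14 measured genes belong to the HIF list, so they are not 2 independent results. The estimated correlation lay below the preset 0.01 for the 26-gene signature (-0.0296), glycogen (-0.0901), oxygen-sensing (-0.0796) and angiogenic (-0.0212) lists. Their lost calls therefore do not show a stronger correlation between their genes. Lists other than the HIF targets and the classifier share members too. Fry called 6 lists. They were the HIF targets (fry adjusted p = 0.000767), the 15-gene classifier (0.00131) and a published 26-gene hypoxia signature (0.00154). The others were oxygen sensing (fry adjusted p = 0.00351), glycogen metabolism (0.00505) and glycolysis (0.0230). The p-values over regions of 1 animal are too small.

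The HIF target list shifted up the most, with a median log2 difference of 1.40 over 37 measured genes, of which 34 were higher (camera adjusted p = 1.05e-32, and adjusted p = 0.00891 with an estimated correlation). Of these genes 5 rose over all genes and 24 rose adjusted over the list alone, led by SLC2A3, IGFBP3, ADM and ERO1A. The count over all genes was 14 without pimonidazole-high replicate 1, 1 without pimonidazole-low replicate 1 and 0 without each of the other 4 arrays in turn. In the 15-gene classifier, 14 genes were measured, 1 rose over all genes (ADM) and 11 rose adjusted over the list alone, with a median of 1.39 (camera adjusted p = 1.56e-17, and adjusted p = 0.0156 with an estimated correlation). A published 26-gene hypoxia signature from head and neck tumours had 22 measured genes, 0 past over all genes and 7 that rose adjusted over the list alone, among them VEGFA, P4HA1, HILPDA and SLC2A1. Its median was 0.48 (camera adjusted p = 4.77e-07, but adjusted p = 0.0552 with an estimated correlation). These 4 genes and ANGPTL4 are also in the HIF list, and without these 5 the median was 0.31 (camera adjusted p = 0.00168, but adjusted p = 0.339 with an estimated correlation), a setting chosen after seeing the data. The p-values over regions of 1 animal are too small.

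All 16 glycolysis genes had a higher mean in pimonidazole-high regions, with a median difference of 0.45 (camera adjusted p = 7.68e-09, but adjusted p = 0.134 with an estimated correlation). None passed over all genes in limma, and 5 passed adjusted over the list alone. Of these, 4 rose: HK2, which encodes a hexokinase, at 2.71 ± 0.47 (SE), PGK1 at 1.47 ± 0.33, GPI at 1.19 ± 0.27 and, named after its value was seen, ALDOC at 0.96 ± 0.24. The other was ENO2, which lay within the range of the negative controls on all 6 arrays, so its difference is not read as a change. In the glycogen list, 1 of 10 genes rose adjusted over the list alone and 0 over all genes: PPP1R3C, a glycogen-targeting phosphatase subunit, at 1.44 ± 0.33. That list's shift (median 0.21, camera adjusted p = 0.0492, fry adjusted p = 0.00505) was lost in camera with an estimated correlation (adjusted p = 0.262 with an estimated correlation). It was also lost without pimonidazole-high replicate 1 (camera adjusted p = 0.0857), 2 (0.0772) or 3 (0.0812), or pimonidazole-low replicate 2 (0.159) or 3 (0.0619), and with quantile normalization (0.0528), centring (0.0514), array weights (0.0559) or the dimmest 25% of genes left out (0.102). Regions of 1 animal make these p-values too small.

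Immediate early genes, which respond within minutes to many stimuli, were higher in all 16 measured cases, with a median of 0.93 (camera adjusted p = 2.15e-10, but adjusted p = 0.194 with an estimated correlation). None rose over all genes in limma, and 7 rose adjusted over the list alone, including ATF3 at 2.83 ± 0.36, FOS at 2.48 ± 0.32, FOSB at 2.13 ± 0.40 and KLF6 at 1.26 ± 0.30. ATF3 and FOS missed the threshold over all genes narrowly (limma adjusted p = 0.0523), and each passed it in 8 of 15 refits. FOS lay within the negative control range on the 3 pimonidazole-low arrays. Of 24 measured genes of the ATF4 and integrated stress response list, 0 rose over all genes and 4 rose adjusted over the list alone: ATF3, DDIT3 (2.17 ± 0.40), PPP1R15A (2.01 ± 0.51) and NUPR1 (1.61 ± 0.36). The list median was 0.25 (camera adjusted p = 0.000175, but adjusted p = 0.307 with an estimated correlation). In the unfolded protein response list, 2 of 19 genes rose adjusted over the list alone and 0 over all genes, PDIA4 at 0.80 ± 0.18 and HERPUD1 at 0.95 ± 0.22, both linked to protein folding or degradation at the endoplasmic reticulum. Its median was 0.34 (camera adjusted p = 0.00153, but adjusted p = 0.194 with an estimated correlation). These p-values, over regions of 1 animal, are too small.

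Oxygen-sensing components had 3 of 11 genes that rose adjusted over the list alone and 0 over all genes: the prolyl hydroxylase genes EGLN3 (1.40 ± 0.20) and EGLN1 (0.65 ± 0.20), whose products mark HIF for degradation, and the HIF antagonist CITED2 (2.01 ± 0.29). EGLN3 lay within the negative control range on the 3 pimonidazole-low arrays, so the size of its difference is uncertain. The list median was 0.26 (camera adjusted p = 0.00899, but adjusted p = 0.194 with an estimated correlation), and the call was lost without pimonidazole-low replicate 2 (camera adjusted p = 0.0677). Among 16 angiogenic factors, ADM rose over all genes, and adjusted over the list alone ADM, PGF (2.39 ± 0.30), VEGFA and EDN1 (1.39 ± 0.40, named after its value was seen) rose. ANGPT1 passed that adjustment with lower signal, but lay within the negative control range on all 6 arrays, so its difference is not read as a change. The list median was 0.20 (camera adjusted p = 0.0133, but adjusted p = 0.194 with an estimated correlation). Its call was lost without pimonidazole-high replicate 1 (camera adjusted p = 0.188) or pimonidazole-low replicate 2 (0.0642), and with array weights (0.0552). With the HIF list's members removed, a setting chosen after seeing the data, neither the oxygen-sensing list (camera adjusted p = 0.247) nor the angiogenic list (0.377) was called, nor was the glycogen list (0.406). The p-values over regions of 1 animal are too small.

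In the NF-kB and inflammatory cytokine list, 2 of 22 genes rose adjusted over the list alone and 0 over all genes, and both encode inhibitors of NF-kB signalling: TNFAIP3 at 2.34 ± 0.30 and NFKBIA at 1.55 ± 0.33. CXCL8, a neutrophil chemoattractant gene, differed by 1.72 ± 0.55 without passing (1.03 without pimonidazole-high replicate 2) and lay within the negative control range on the 3 pimonidazole-low arrays. The list median was 0.19 (camera adjusted p = 0.0492, but adjusted p = 0.470 with an estimated correlation). That call was lost without pimonidazole-high replicate 2 (camera adjusted p = 0.138) or 3 (0.235), or pimonidazole-low replicate 2 (0.159) or 3 (0.0504), and with centring (0.0514), while the list mean of 0.32 became 0.55 without pimonidazole-high replicate 1 (0.000251). Interferon-stimulated genes had a median of 0.41 over 28 genes with 0 past either adjustment, and OAS2 differed by 1.09 ± 0.29 and BST2 by 0.91 ± 0.30 (camera adjusted p = 0.000633, but adjusted p = 0.587 with an estimated correlation). Without pimonidazole-high replicate 1 the interferon call was lost (mean 0.13 in place of 0.34, camera adjusted p = 0.467), and the mean was 0.51 without pimonidazole-high replicate 3 (4.98e-06) and 0.21 without pimonidazole-low replicate 3 (0.0263). All p-values over regions of 1 animal are too small.

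Squamous differentiation genes, which build the cornified envelope of stratified epithelium, had a median difference of 0.46 over 28 genes, with 0 past over all genes and 1 that rose adjusted over the list alone, SPRR3 at 2.85 ± 0.63 (camera adjusted p = 0.00803, but adjusted p = 0.679 with an estimated correlation). The list mean of 0.54 became 1.26 without pimonidazole-high replicate 1 (camera adjusted p = 5.10e-19), and the call was lost without pimonidazole-high replicate 2 (mean 0.26, 0.218) or 3 (mean 0.11, 0.773). The mean signal of the list was 9.96 in pimonidazole-high replicate 1, 11.97 in replicate 2 and 12.27 in replicate 3, against 10.61 to 11.06 in the pimonidazole-low regions. Of 18 basal urothelial markers listed, KRT6A, KRT6B, KRT17, CDH3, TP63 and COL17A1 were not analysed here. Of 21 luminal urothelial markers listed, KRT20, KRT7 and ERBB2 were not. The tests of the urothelial lists do not cover these genes. Neither basal urothelial markers (median -0.03, 12 genes, 0 past either adjustment; camera adjusted p = 0.611) nor luminal urothelial markers (median 0.23, 18 genes, 0 past either adjustment; camera adjusted p = 0.0507) shifted past the threshold, though the luminal list did without pimonidazole-low replicate 1 (0.0239) or pimonidazole-high replicate 2 (0.0352), with scaling to the 75th percentile (0.0469), and without the dimmest 25% of genes (0.0403) or genes below the median brightness (0.0282). These p-values, over regions of 1 animal, are too small.

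The 3 lists that shifted down were metallothioneins, oxidative phosphorylation and the mitotic cell cycle. Metallothioneins, small metal-binding proteins, had a lower mean in pimonidazole-high regions for 8 of 8 genes, of which MT1X (-0.01) turned to 0.02 when each array was centred, with a list median of -0.58 (camera adjusted p = 0.000212, but adjusted p = 0.262 with an estimated correlation). None fell over all genes, and MT1F and MT1E (-0.71 ± 0.22) fell adjusted over the list alone. MT1E lay within the negative control range on the 3 pimonidazole-high arrays and on pimonidazole-low replicate 2. Metallothionein genes are close relatives whose probes can share signal, so their separate values are uncertain. In the oxidative phosphorylation list 34 of 44 genes had a lower mean and 0 passed either adjustment, with a median of -0.20 and examples NDUFS7 at -1.04 ± 0.30 and COX6A1 at -0.69 ± 0.20 (camera adjusted p = 0.0108, but adjusted p = 0.604 with an estimated correlation). In the mitotic list 25 of 31 genes had a lower mean and 0 passed either adjustment, with a median of -0.21 and BIRC5, which encodes survivin, at -1.28 ± 0.36 (camera adjusted p = 0.0187, but adjusted p = 0.262 with an estimated correlation).

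Both of these calls were lost in fits that left out an array and with some processing settings. The oxidative phosphorylation call was lost without pimonidazole-high replicate 1 (camera adjusted p = 0.135) or 2 (0.0925) or pimonidazole-low replicate 2 (0.510), and the mitotic call without pimonidazole-high replicate 1 (0.0889) or 3 (0.0546) or pimonidazole-low replicate 2 (0.170). With array weights both were lost (oxidative phosphorylation 0.0991, mitotic 0.0506), and the mitotic call was also lost without genes below the median brightness (0.0620). Without pimonidazole-high replicate 3 the oxidative phosphorylation mean of -0.17 became -0.26 (camera adjusted p = 0.000293). The p-values over regions of 1 animal are too small.

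**Figure D3:**
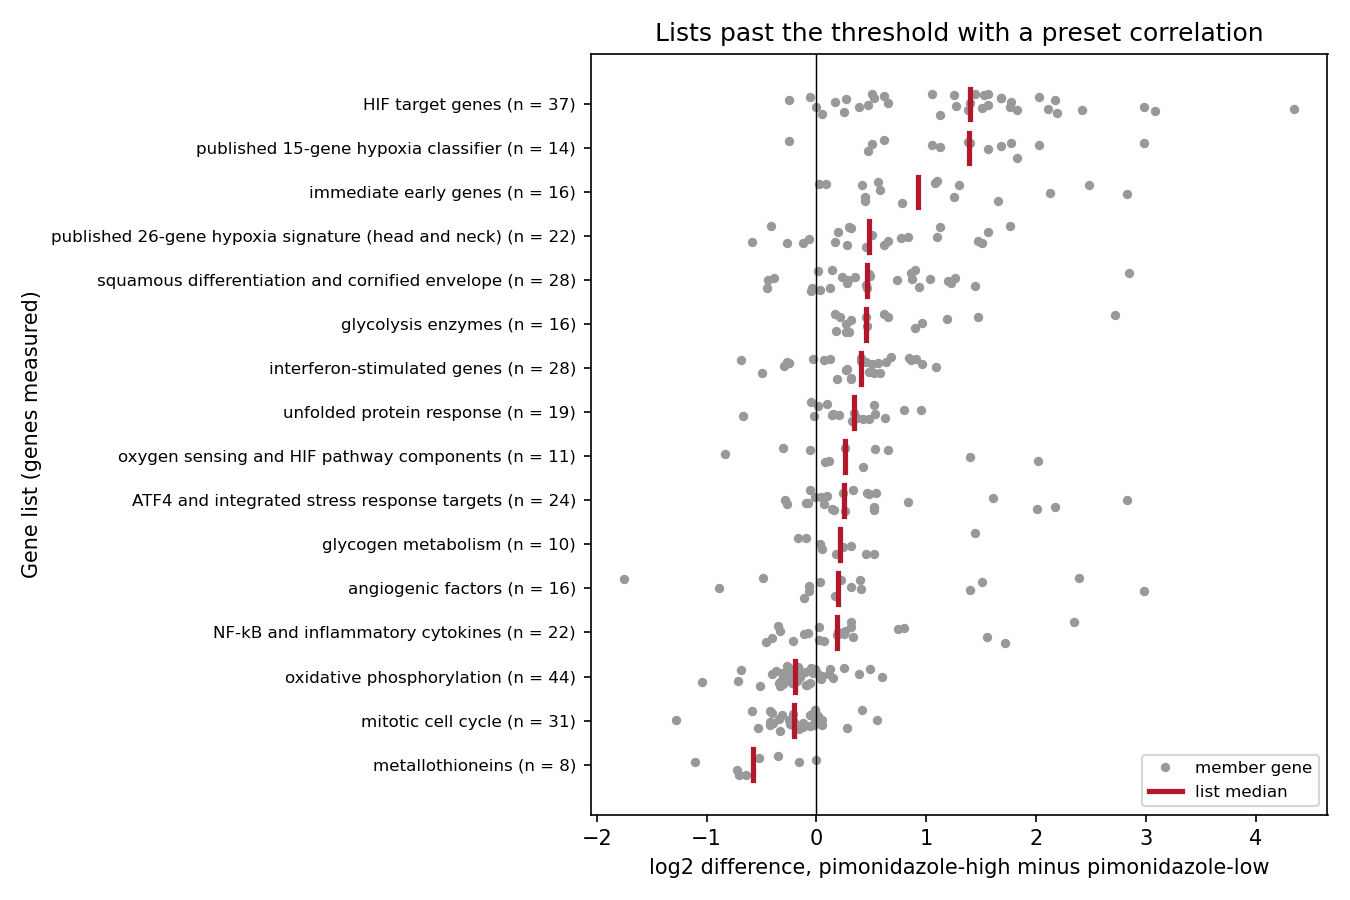
Difference in mean log2 signal between pimonidazole-high and pimonidazole-low regions (horizontal axis) of each measured member (grey points) and the median (red bars) of the 16 lists past the threshold in camera with a preset correlation, each with its number of genes. The HIF target median lies at 1.40 and the metallothionein median at -0.58, and 2 of the 16 lists (HIF targets and the 15-gene classifier) kept their call with an estimated correlation.

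Markers of host cells were measured on the human arrays, where mouse transcripts can hybridise in part. Markers above the negative control range numbered 3 of 14 endothelial, 4 of 19 myeloid and 8 of 14 fibroblast and pericyte genes. Group means of the lymphocyte, erythroid, skeletal muscle, adipocyte and mast cell lists were 4.04 to 4.84, below the arrays' limits of 6.22 to 6.92. Lists this dim could hardly shift, so a list without a call says little about host cells. None of the 8 host marker lists shifted past the threshold. The fibroblast and pericyte list was nearest (median -0.21, 14 genes, 0 past over all genes; camera adjusted p = 0.0568), and FAP and COL6A3 (-1.18 ± 0.31) fell adjusted over the list alone. COL1A1 differed by -0.35 ± 0.38, COL1A2 by -0.44 ± 0.42 and DCN by 0.11 ± 0.31. The endothelial list had a median of -0.14 over 14 genes (camera adjusted p = 0.424) and the myeloid list 0.13 over 19 genes (0.259), both with 0 genes past either adjustment. In the skeletal muscle list TNNT3 (1.43 ± 0.34) and MB (1.22 ± 0.31), which encodes the oxygen carrier myoglobin, rose adjusted over the list alone and not over all genes, and MB lay within the negative control range on the 3 pimonidazole-low arrays. The list median was -0.04 and its mean 0.15 (camera adjusted p = 0.687). The myeloid list was called without pimonidazole-high replicate 1 (camera adjusted p = 0.00573), and the fibroblast list without pimonidazole-low replicate 1 (0.0328), pimonidazole-high replicate 3 (0.00629) or genes below the median brightness (0.0177). These p-values, over regions of 1 animal, are too small.

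The other lists that did not shift had camera adjusted p between 0.0511 for DNA replication and S phase and 0.978 for cholesterol synthesis. Cytosolic ribosomal proteins had a median of 0.09 over 38 genes, and were called without pimonidazole-high replicate 1 (camera adjusted p = 0.0221) or pimonidazole-low replicate 2 (0.0121). The DNA replication list (median -0.15) was called without pimonidazole-high replicate 3 (0.0149) or pimonidazole-low replicate 3 (0.00939), and with centring (0.0498) or scaling to the 75th percentile (0.0469). The histone list (median -0.13) was called without pimonidazole-high replicate 2 (0.00415). Collagen modification (median 0.08) was called without pimonidazole-high replicate 1 (0.0389), and the DNA repair genes RAD51C (-0.76 ± 0.19) and EXO1 (-0.75 ± 0.22) fell adjusted over the list alone and not over all genes. In the fatty acid list the median was -0.23, the mean 0.10 and the camera direction down, while PLIN2, a lipid droplet coat gene (1.68 ± 0.21), and HILPDA (1.76 ± 0.38) rose adjusted over the list alone and not over all genes. In the autophagy list, called without pimonidazole-high replicate 2 (camera adjusted p = 0.0490), the median was -0.09 and the mean 0.19, and BNIP3L (1.05 ± 0.19) and SQSTM1 (1.29 ± 0.27) rose adjusted over the list alone and not over all genes. The median and the mean also differed in sign for pH regulation (0.17 and -0.09), erythroid markers (-0.02 and 0.10) and lymphocyte markers (0.04 and -0.06). All of these p-values, over regions of 1 animal, are too small.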

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

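The removal of HIF list members from the other lists was chosen only after the data were seen. The HIF list kept its direction and call in every setting run on it, with a mean of 1.26 to 1.53. The 8 genes past the threshold kept their direction in all 15 refits and were all past it in 10. Of 16 called lists 8 kept the call in every refit and 8 lost it in at least 1 (glycogen metabolism in 9), and 8 uncalled lists were called in at least 1. Of 169 other named genes that were followed over the refits, 15 passed in at least 1 refit and 4 changed sign. Genes named after their values were seen, apart from SLC2A14, were not in this count, and MT1X among them turned to 0.02 with centring. Of 3437 alternative values, 3172 kept direction and side of the threshold or, for counts, stayed within a fixed factor of the main count. Of the others, 97 lost a call, 83 gained one and 39 were counts that moved further. In 46 the direction changed, 0 of them for a called result: in 29 the value changed sign, and in 17 only the direction of the list test did. The cause was not tested except where fewer genes or arrays were used.

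The count of genes was 17 with centring (all higher), 16 with scaling to the 75th percentile (all higher), 17 without the dimmest 25% of genes, 15 without genes below the median brightness, 19 with an intensity trend, 22 with a robust prior (20 higher and 2 lower), 24 with array weights and 28 at adjusted p under 0.1. With 1 array left out it ranged from 0 to 156 (higher 0 to 137, lower 0 to 19). Named hypoxia genes past the threshold over all genes were 2 with a trend, 2 with a robust prior, 3 with array weights and 0 to 4 with 1 array left out, and over the list alone 8 to 10. Called lists numbered 2 with an estimated correlation and 6 with fry. Without HIF list members, glycogen metabolism (adjusted p = 0.406), NF-kB (0.0674, with 0 members removed, so only the lists it was adjusted with changed), angiogenic factors (0.377) and oxygen sensing (0.247) lost the call.

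Among the lists and genes followed over the refits, values that changed sign were as follows. Epithelial-mesenchymal transition was -0.00184 with quantile normalization and -0.0150 with array weights. Cholesterol synthesis was 0.0128 with centring and 0.00344 without genes below the median brightness. MKI67 was 0.000747 with centring. Fatty acid synthesis was -0.226 without HIF list members, and collagen modification was -0.0397 without them. Only the direction of the test changed, and not the sign of the mean, for cholesterol synthesis (-0.0108 without the dimmest 25% of genes), fatty acid synthesis (0.0976 without these, 0.185 without genes below the median brightness and 0.0976 with fry), antigen presentation (-0.0500 without genes below the median brightness) and skeletal muscle (0.0627 with array weights).

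With 1 array left out, the ranges of results whose sign or test direction changed were -0.284 to 0.0223 for pH regulation, -0.439 to 0.116 for histones, -0.0972 to 0.0727 for cholesterol synthesis, -0.00290 to 0.184 for fatty acid synthesis, 0.0670 to 0.270 for skeletal muscle, -0.000912 to 0.181 for ribosomal proteins, -0.225 to -0.000739 for basal urothelial markers and -0.198 to 0.0375 for antigen presentation. They were -0.170 to 0.287 for collagen modification, -0.158 to 0.118 for epithelial-mesenchymal transition, -0.0994 to 0.0106 for lymphocytes, -0.100 to 0.0356 for adipocytes, -0.195 to 0.101 for HIF1A, -0.107 to 0.0754 for MKI67, -1.14 to 0.672 for DSG3 and -0.0720 to 0.711 for CA12.

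No paired analysis was possible because the labels do not link a pimonidazole-high to a pimonidazole-low region. The alternative log offset was not run, since the deposited values are already log2. Counts adjusted over the list alone were refitted for the named hypoxia genes and not for the other lists. Only 46.8% to 52.4% of genes per array lay above the range of the negative controls, which limits what can be read from dim genes.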

Other observations

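The tests of the HIF list (centring, random lists, 1 array left out, splits), of myeloid markers, of centring for immediate early genes, of bright HIF target genes, of FAP (endothelial markers and centring) and all tests of the first principal component were chosen only after the result was seen. The pimonidazole-high regions differed among themselves. Squamous differentiation genes had a list mean of 9.96 in pimonidazole-high replicate 1, 11.97 in replicate 2 and 12.27 in replicate 3. Among genes chosen after their values were seen, LCE3D, a cornified envelope gene, had 5.70, 12.08 and 11.95 in these regions, and TGM1, which encodes a transglutaminase that crosslinks that envelope, had 5.68, 9.16 and 10.07. S100A12, which encodes a calcium-binding protein, had 8.71, 13.76 and 13.62. The first principal component held 33.9% of the variance and placed pimonidazole-high replicate 1 at -42.5, replicate 2 at 39.9 and replicate 3 at 33.3, with the pimonidazole-low regions at -18.0, -2.52 and -10.3.

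SLC2A14, chosen after its value was seen, differed by 2.93 ± 0.36 (SE, limma adjusted p = 0.0523), and it is a close paralog of SLC2A3, so their probes can share signal. Among 3498 probe sets unnamed here, 0 passed in a joint limma fit, 293 had an unadjusted p under 0.05, and the named genes past the threshold were still 8.

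HIF target genes were higher in pimonidazole-high regions. Against an offset shared by all genes of an array as the whole cause, the array medians spanned only 6.45 to 6.59. Centring, which moves all genes of an array alike, left the list median at 1.42 and could hardly have changed it. Against a bias with brightness, the list median lay at percentile 100 of 10000 random lists matched on signal, whose highest median was 0.251, although such lists ignore correlation between genes. Against 1 deviating region, the lowest median with 1 array left out was 1.21, without pimonidazole-high replicate 1. A response to low oxygen, the difference the staining marks, may underlie the pattern, but all regions come from 1 animal and no test here measured oxygen itself.

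Immediate early genes had a higher list mean in pimonidazole-high regions, a shift not called with an estimated correlation (adjusted p = 0.194 with an estimated correlation), and in limma 0 of 16 genes passed over all genes and 7 adjusted over the list alone. Against an offset shared by all genes of an array, the list median was 0.951 after centring. That step moves all genes of an array alike and could hardly have changed the median, since array medians spanned only 6.45 to 6.59. Array quality stays open: the control AUC differed by -0.195 pooled SD, but it reads control probe sets alone, and the hybridisation controls differed by 1.33 and the percent of genes above the negative range by -1.53 pooled SD. More host myeloid cells stay open too: 4 markers had a median of 0.442, but S100A8 and S100A9 are also in the squamous list, which leaves ITGAM (0.15) and FCGR3A (1.23, and 0.75 to 1.99 with 1 array left out, the highest without pimonidazole-high replicate 1), too few to decide. A response to low oxygen and a response to handling of the tissue stay open and were not tested.

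The first principal component parted pimonidazole-high replicate 1 from replicates 2 and 3. A candidate explanation is unequal squamous differentiation. That list's median loading ranked 1 of 42 lists and lay at percentile 100 of random lists. The loading restates the spread between these regions that the component describes, and random lists ignore correlation between genes, so it does not test the explanation. Against array quality, the control AUC of replicate 1 lay at a distance of 0 outside the range of the other 5 arrays, a weak check, but its mean correlation with its group was the lowest of the 6 arrays (0.977), as the pattern itself would give. Against an offset of whole arrays, the gap of the squamous list between replicate 1 and the lower of replicates 2 and 3 was 1.92 after centring. Array medians spanned only 6.45 to 6.59, so centring could hardly have closed that gap. No group of the design parts these regions, and the HIF target list mean did not part replicate 1 (10.56) from replicates 2 (10.60) and 3 (10.50), although its median loading ranked 6 of 42 lists.

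For the split tests, 10 splits of the 6 arrays are too few for a share under 0.05. The real split gave 8 genes and the highest other 0, and 1 of the 10 splits gave as many. It gave a HIF list median of 1.40 against 0.489 (1 split as large), 16 lists against 11 (1 split as large) and 9 named hypoxia genes over the list alone against 0 (1 split as large). The other splits gave 5 to 11 lists with the preset correlation. At an unadjusted p under 0.05 the split that joins pimonidazole-high replicate 1 with pimonidazole-low replicates 1 and 3 gave 1556 genes, against 1531 for the real split.

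Other tests are given as values. Over 16 glycolysis genes, Spearman's rho across genes of the log2 difference and the pimonidazole-low mean was -0.429 (permutation p = 0.0975), and over HIF target genes rho was 0.333. Genes are not independent replicates. The 95th percentile of the absolute log2 difference over the 142 brightest genes was 0.487 times that over 3362 genes of middle brightness, and 3 bright HIF target genes (BNIP3L, SLC2A1 and TMEM45A) had a median of 1.05. FAP differed by -2.89 after centring, and 3 endothelial markers above the negative range went both ways (EGFL7 0.37, ENG -0.72 and ERG -1.27, with a median of -0.72). Over the refits EGFL7 ranged from 0.25 to 0.46, ENG from -1.21 to -0.33 and ERG from -1.82 to -0.70. The fibroblast marker S100A4 differed by 0.27 ± 0.33 (SE).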
